A study of Homo sapiens with 6 samples.

How the data were processed

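PAR-CLIP with an anti-Argonaute antibody was done by the authors on HK2 cells, with IgG as a control pull-down. Per the labels' protocols, cells were serum starved for 24 h, exposed to TGF-beta1 at 20 ng/mL for 24 h, given 100 uM 4-thiouridine for the last 20 h, and irradiated at 365 nm. Lysates were treated with DNase and micrococcal nuclease, and complexes of 100 to 150 kDa were cut from a gel. Libraries came from a small RNA kit with selection of 80 to 150 nt cDNA. The submitters' processing notes name STAR 2.7.1a, bcl2fastq 2.20.0.422, bedtools and the hg38 genome, and the file headers name GENCODE release 27. The program that called crosslinks and its filters are not given in the sources used here. No molecular identifiers are named, so reads are not counted as independent molecules and the intervals below cover counting error only.

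The deposited table gives, per site and library, 2 values in RPM, scaled to the total reads of the library, per the file headers: the reads that cover the crosslinked position and the reads that carry a crosslink there. It also gives the authors' microRNA seed annotation, with a score per seed that the authors computed as microRNA reads scaled to the library total and rounded. A second deposited list holds the same 16230 positions with a score that is 1 at every site. Positions in both agree for all 16230 sites. Another 4 columns of per-sample values, which name RNA-seq samples and not samples of this series, were not used. The header calls the treated average of crosslinked reads an average of coverage; that column was not used either.

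All RPM values were whole multiples of the value of 1 read in their library (100% within 0.1 reads), so reads and depth were recovered: 1714445, 1926255, 5293208 and 3415699 reads for control replicates 1 and 2 and TGF-beta1 replicates 1 and 2. The coverage value was 0 at every site where a library had no crosslinked read, in all 4 libraries. Crosslinks were in 23.0 to 31.0% of covering reads at sites crosslinked in every library. Crosslinked reads were therefore used for the reported values, and coverage only in alternatives. Every site had a crosslink in at least 2 libraries; 1874 sites had none in either control library and 193 none in either treated library, so the list follows the deeper treated libraries more closely.

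The plan fixed before the data were examined used edgeR on counts, and limma where files hold normalized values. Because the values are RPM, the reported test is limma on log2(TMM-scaled RPM + 1), with a variance trend, two-sided, and Benjamini-Hochberg adjusted p under 0.05. TMM factors came from the recovered reads and ranged over sites from 0.614 to 1.509 and over genes from 0.666 to 1.385. Sites and genes were kept by edgeR's filterByExpr (minimum count 10), which left 1059 sites and 1266 genes. Gene values are sums over the sites with the same gene name; 144 names that join overlapping genes were kept as they stand. Fold changes in the text are ratios of group means of scaled RPM, and log2 differences are on the log2(value + 1) scale, which understates the change of low genes. With limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and R 4.3.3, family sets of at least 10 sites and lists of at least 5 genes were tested with camera (preset correlation 0.01). The plan did not state whether limma should model the spread as a trend with the level. Before that was settled, call counts had been seen for crosslinked reads and for coverage at all sites, each by limma with the trend, without it and without TMM, and by edgeR. The trend was kept with 39 genes and 76 sites in view, against 3 and 25 without it, so the number of calls is not independent of that choice. The edgeR quasi-likelihood test on recovered reads, added after the data were seen, called 82 sites and 48 genes.

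Control and treated libraries share replicate numbers, but deviations from group means of libraries with the same number correlated at 0.117 over sites and 0.131 over genes with only 2 pairs, so the numbers were not taken as pairs. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Groups of 2 leave limma with few degrees of freedom and make the exact permutation test unable to pass 0.05.

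The planned seed test needs a genome of the files' build for windows of 20 nt either side and control windows 150 nt away, and was not run. In its place, chosen after the data were seen, the 31 nt window that the table gives around each crosslinked T (15 nt either side) was compared with dinucleotide-preserving shuffles (Python 3.11.15, numpy 2.4.6, numba 0.67.0). The families and their mature sequences were fixed beforehand. Alternatives of the seed test first had fewer shuffles, whose smallest p was 0.01; intronic sites then gave 0 families and coding sites 20. Their shuffles were raised to the number of the reported test after those counts were seen. A family counted as listed where its nucleotides 2 to 8 equal a seed in the authors' table. The planned comparison of Argonaute with IgG libraries was not run, since no value per IgG library is analysed here. Gene names are those of the table; 4107 of 4218 names of a single gene were found as a symbol or synonym in the RefSeq table of GRCh38.p14.

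Each step was tested on simulated data. For the fits, reads were drawn at the real depth, with a spread that followed the level alone and no difference in composition between libraries. For genes, with 200 of 1266 changed, limma recovered 76% of 4-fold and 18% of 2-fold changes with 0% false calls. For sites, with 200 of 1059 changed, it recovered 58% and 14%, with 1.4% false calls. False calls under another spread or composition were not tested. For camera, log2 values of 1266 independent genes were drawn with the same spread for all, and a set of 15 was shifted by 1 log2 unit. Among 50 such runs camera called the shifted set in 50 and an unchanged set in 5, at an unadjusted p under 0.05. Independent genes do not test the preset correlation. The lists called in the real data had smaller mean log2 differences, 0.584 to 0.715. The seed test recovered an excess of 127.7 of 127 planted matches in 6332 windows. That run had too few shuffles for a single family to pass the adjusted threshold. Its 0 calls of other families therefore do not test for false calls.

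Genes named in the text are FRMD6 with its sites, the 10 smallest p among higher and among lower genes with adjusted p under 0.05 and no overlap between groups, up to 4 passing members of each list or its 2 most crosslinked tested members where none passed, the 10 most crosslinked genes, and the miR-17 family; SMAD7 and the EGR2 and SEMA7A sites were named after their values were seen, to complete a count. A few genes and sites that this rule picks are not reported here, but stay in the counts and set tests. Alternatives covered scaling, the low-count filter, the replicate number as a block, leaving out each library, 3' UTR sites only, window and match type, and the set test; pseudocounts of 0.5 and 2, no variance trend, coverage at sites crosslinked in every library or at all sites, and thinning to the shallowest library in 20 draws were added after the data were seen.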

Results

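Argonaute-bound RNA was mapped by PAR-CLIP in HK2 cells, an established line of human kidney proximal tubule epithelium. In PAR-CLIP, cells take up 4-thiouridine, ultraviolet light crosslinks it to bound protein, and the crosslinked position is read as a base change after reverse transcription. The series holds 2 anti-Argonaute libraries from control cells, 2 from cells given TGF-beta1 at 20 ng/mL for 24 h, and 2 IgG libraries. Values per library were analysed for the 4 Argonaute libraries. The IgG libraries were not analysed here, so no background level stands beside the values. The table lists 16230 predominant crosslink sites in 4361 named genes on the hg38 genome. Library depth, recovered from the deposited values, was 1714445 and 1926255 reads for control replicates 1 and 2, and 5293208 and 3415699 reads for TGF-beta1 replicates 1 and 2. At the listed sites these libraries held 36958, 53835, 74969 and 72206 crosslinked reads, with a median of 7 per site over the 4 libraries. Across the 6145 sites crosslinked in every library, log2 values correlated at 0.706 between the controls, 0.807 between the treated libraries and 0.694 to 0.729 between groups. These correlations are across sites, which are not independent replicates.

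The first comparison asked where Argonaute crosslinks lie in transcripts, and whether this differs after TGF-beta1. The 3' UTR, the usual location of microRNA target sites, held 6332 of the sites. It took 62.7% ± 5.29 of crosslinked reads in control cells (SD, n = 2) and 58.1% ± 3.27 in treated cells. Coding sequence held 17.1% ± 0.84 and 19.2% ± 0.15, introns 8.22% ± 2.07 and 9.80% ± 1.64, and annotated non-coding RNA 6.23% ± 2.05 and 7.04% ± 1.77. None of these 4 shares was shown to differ. An exact two-sided permutation test gave p = 0.667 for the 3' UTR and p = 0.333 for coding sequence, and 0.33 is the smallest p that 2 libraries against 2 can give.

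The most crosslinked gene was DCBLD2, a transmembrane receptor-like protein, at 331 ± 50.2 scaled RPM (crosslinked reads relative to library depth) in control and 400.5 ± 63.1 in treated cells. The nuclear non-coding RNA MALAT1 stood at 273 ± 126 and 302 ± 133. PEG10, FN1, IRS2, CDKN1B, ZFP36L1 and NEAT1 were also among the 10 most crosslinked genes. The insulin receptor substrate IRS2 stood at 155 ± 31.3 and 140.1 ± 13.2, and the cell cycle inhibitor CDKN1B at 167 ± 5.54 and 113 ± 20.2. The RNA-binding protein ZFP36L1 stood at 119 ± 4.10 and 157 ± 8.42, and the non-coding RNA NEAT1 at 158 ± 45.2 and 109 ± 27.7. None of DCBLD2, MALAT1, IRS2, CDKN1B, ZFP36L1 and NEAT1 passed the test between groups. With 3' UTR sites only, CDKN1B passed as lower (limma adjusted p = 0.0422) and ZFP36L1 as higher (limma adjusted p = 0.00708). CDKN1B and NEAT1 also passed as lower with the replicate number as a block.

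The second question was which microRNA families have seed matches at the crosslinks. The planned control windows need a genome, so the 31 nt windows of the table were compared with dinucleotide-preserving shuffles of themselves, a test chosen after the data were seen. Of 47 families, 32 had more 7-nt matches (mature nucleotides 2 to 8) in 3' UTR windows than in shuffles, and 0 had fewer. The test was a two-sided permutation test with Benjamini-Hochberg adjusted p under 0.05; at an unadjusted p under 0.05 the counts were 33 and 0. The let-7 family had the largest excess, 105 windows against 6.5 in shuffles, or 16.26-fold. The miR-17 family (miR-17-5p, miR-20a-5p, miR-93-5p and miR-106b-5p), which holds the microRNAs in the title of the series, matched 154 windows against 24.9, or 6.18-fold. Its permutation p of 0.002 is the smallest that these shuffles can give (adjusted p = 0.0035). The excess was 7.82-fold for miR-25 and miR-92, 7.35-fold for miR-30, 7.24-fold for miR-22, and 6.68-fold for miR-200b, miR-200c and miR-429. Of families whose seed the authors listed as expressed 21 of 26 passed, of unlisted families 11 of 15 (with miR-29, which the authors list by a seed offset by 1 nt), and of families typical of other tissues 0 of 6, with a median of 0.91-fold. Of those 6, miR-142-3p stood at 1.84-fold (permutation p = 0.042, adjusted p = 0.0598). It passed with 10 nt either side (2.15-fold, adjusted p = 0.0285) and when 8mer and both kinds of 7mer match were counted (2.09-fold, adjusted p = 0.0035). In coding sequence 22 families had more matches and 1 had fewer. In introns 7 had more, among them let-7 at 18.36-fold (adjusted permutation p = 0.0235) and the miR-17 family at 2.71-fold, 18 windows against 6.6 (adjusted permutation p = 0.0235).

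**Figure D1:**
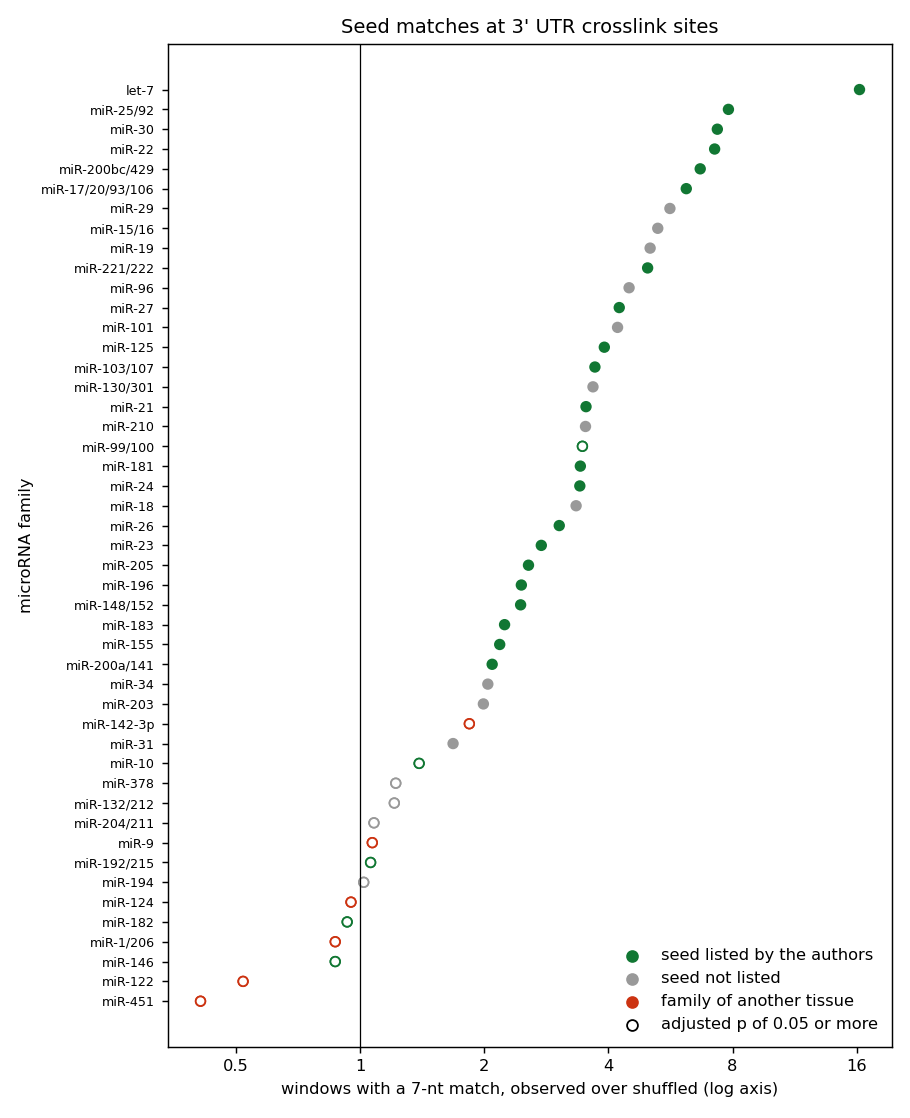
Each point is one microRNA family, and the x axis gives the number of 3' UTR windows with a 7-nt match divided by the number in shuffled windows, on a log axis. Filled points passed the permutation test; let-7 lies farthest right at 16.26-fold, the miR-17 family at 6.18-fold, and all 6 families of other tissues are open points.

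The matches lay next to the crosslinked base. For families listed by the authors, 71.5% of 1783 matches (95% Wilson interval 69.4 to 73.6) began 0 to 3 nt downstream of the crosslinked T. The share was 85.3% of 156 matches for the miR-17 family, and 43.8% of 48 matches (30.7 to 57.7) for families of other tissues. In the authors' annotation, 3' UTR sites with an adjacent 7-nt match had a median of 18 reads against 7 at 3' UTR sites without a match. Their geometric mean was 2.63-fold higher (permutation test over sites, p = 1e-05, the smallest it can give). Across the 26 listed families, the log2 excess over shuffles rose with the authors' microRNA read number per seed. Pearson's r was 0.54 (permutation p = 0.0038), Spearman's rho 0.56 (permutation p = 0.0037), and r was 0.53 without the 2 families farthest from the median abundance. Families are not independent replicates, since some seeds overlap.

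**Figure D2:**
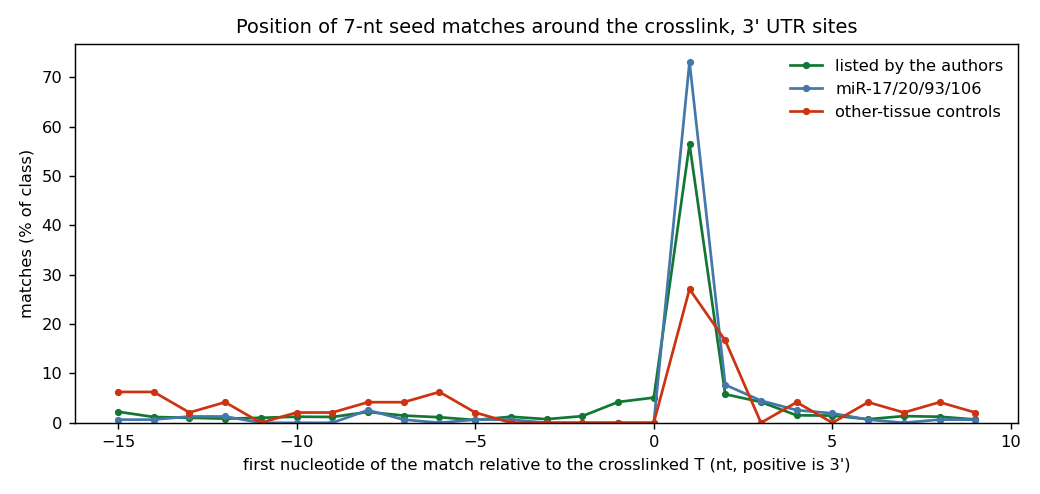
The x axis gives the position of the first nucleotide of each 7-nt match relative to the crosslinked T in nt, and the y axis the percent of matches of that class in 3' UTR windows. All 3 classes peak 1 nt downstream, at 73.08% of matches for the miR-17 family, 56.42% for the families listed by the authors and 27.08% for the families of other tissues.

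The main comparison asked which genes gained or lost Argonaute crosslinks after TGF-beta1. FRMD6, a FERM-domain protein that acts upstream of the Hippo pathway and is named in the title of the series, rose 5.49-fold. Summed over its sites it went from 13.02 ± 1.21 scaled RPM in control cells to 71.5 ± 0.375 in treated cells (SD, n = 2; log2 difference 2.37 ± 0.23 SE; limma adjusted p = 0.000449). PMEPA1, an inhibitor of TGF-beta signalling, rose 6.08-fold from 8.46 ± 0.232 to 51.4 ± 6.71, and INHBA, a subunit of activin, 4.32-fold from 43.2 ± 9.45 to 187 ± 18.1. The matrix protein fibronectin, FN1, rose 3.43-fold from 86.9 ± 9.35 to 298 ± 15.4; all 3 of these genes had the same adjusted p as FRMD6. UGCG, which makes glucosylceramide, fell 3.67-fold from 189 ± 22.9 to 51.6 ± 0.326 (adjusted p = 0.000449). PARD6B, an apical polarity protein, fell 3.33-fold from 70.9 ± 0.600 to 21.3 ± 0.454 (adjusted p = 0.00229). In all, 39 of 1266 tested genes passed, 20 higher and 19 lower, and 79 higher and 96 lower had an unadjusted p under 0.05.

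Among the other genes chosen by rank, the Notch ligand JAG1 rose from 3.14 ± 3.38, on 10 and 2 control reads, to 31.4 ± 0.527. Its log2 difference of 3.26 became 4.203 without control replicate 1 and 2.295 without control replicate 2, and 1.76 with 3' UTR sites only. With DESeq2 it did not pass (adjusted p = 0.0573). The fatty acid desaturase SCD rose 2.42-fold from 46.4 ± 0.685 to 112 ± 14.8. The semaphorin SEMA7A rose 9.18-fold from 1.115 ± 0.013, on 2 and 3 control reads, to 10.2 ± 0.025. With so few control reads its small SDs do not measure precision. The adhesion molecule AMIGO2 rose 2.52-fold from 23.2 ± 0.014 to 58.6 ± 6.17, and the matrix protein TGFBI 4.22-fold from 4.27 ± 0.212 to 18.05 ± 2.66. Among lower genes, the arrestin-domain protein ARRDC3 fell 3.45-fold from 40.2 ± 1.75 to 11.7 ± 3.24 and AHNAK 2.94-fold from 52.7 ± 4.50 to 17.9 ± 2.86. The integrin ITGB8, which takes part in activating latent TGF-beta, fell 12.3-fold from 12.2 ± 2.38 to 0.993 ± 1.00, on 6 and 1 treated reads. Its log2 difference of -2.81 became -3.484 without TGF-beta1 replicate 1. ZFHX4 fell 3.08-fold from 30.7 ± 1.16 to 9.95 ± 1.23. The imprinted, retrotransposon-derived PEG10 fell 2.096-fold from 268 ± 17.4 to 128 ± 13.8. The hydroxylase ASPH fell 3.41-fold from 23.7 ± 1.47 to 6.96 ± 1.02, and ANKRD33B 5.10-fold from 18.8 ± 5.43 to 3.69 ± 1.60. Their adjusted p ranged from 0.0104 for ARRDC3, AHNAK and JAG1 to 0.0154 for ANKRD33B.

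These changes are relative to the typical gene: without TMM scaling the median gene lay at -0.45 on the log2 scale, and 6 higher and 23 lower genes passed. Of the genes above, FN1, INHBA, SCD, AMIGO2 and TGFBI did not pass there (adjusted p = 0.133, 0.0512, 0.54, 0.537 and 0.168). ZFHX4 did not pass with 3' UTR sites only (adjusted p = 0.0971). The calls rest on few libraries and on the model of the spread. By limma, 0 genes passed without control replicate 1 (105 higher and 73 lower at an unadjusted p under 0.05), 0 without control replicate 2 (105 and 68), 11 without TGF-beta1 replicate 1 and 17 without TGF-beta1 replicate 2. Only 3 genes passed when the spread was not modelled as a trend with the level, a setting that was settled after both counts were seen, 4 passed without the filter on low counts, and with read coverage at all sites 25 passed. These 25 included 17 of the 39 called genes. With that coverage the log2 differences were larger for FRMD6 (3.142 against 2.37), PMEPA1 (3.497 against 2.465), JAG1 (5.284), TGFBI (4.049 against 1.846) and ITGB8 (-3.961). With read coverage at sites crosslinked in every library 103 genes passed, among them 36 of the 38 called genes present. There the log2 difference of SEMA7A was 1.737 against 2.408, but it was 3.218 with DESeq2.

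**Figure D3:**
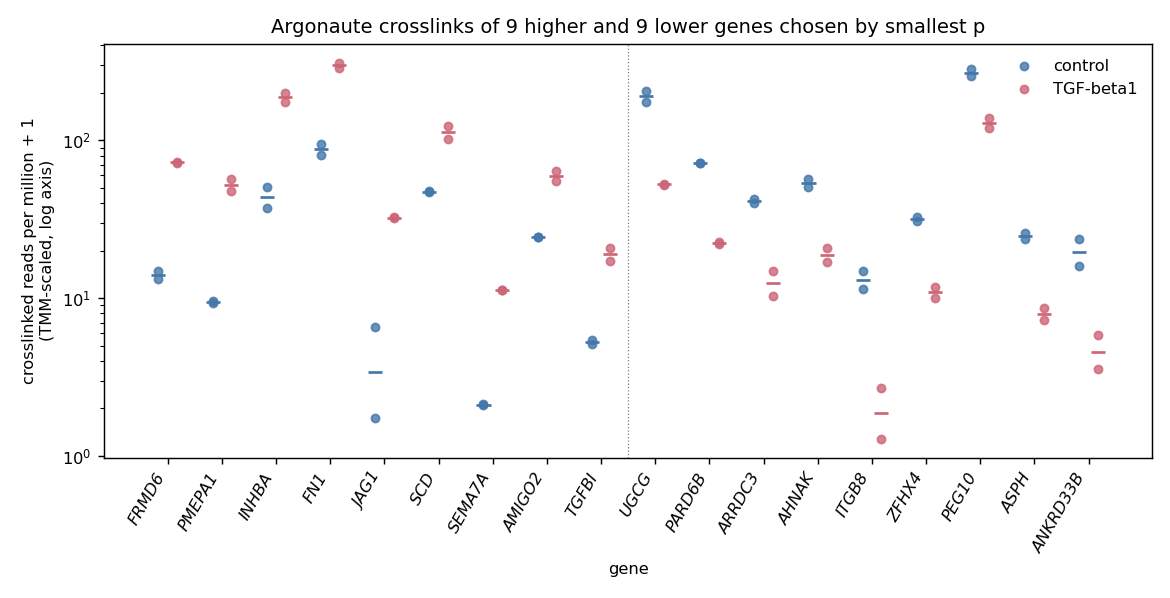
The y axis gives TMM-scaled crosslinked RPM plus 1 on a log axis, with a point for each library and a line at the mean of the log values, for control and TGF-beta1 cells. The 9 genes left of the dotted line were higher and the 9 right of it lower in treated cells; genes were chosen so that the groups do not overlap, as 0.33 of genes would by chance.

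By the lists fixed before the data were examined, the TGF-beta and SMAD pathway list stood higher as a set: 5 of its 15 tested members rose, 0 fell and 10 did not pass (camera with a preset correlation, adjusted p = 0.00105), but was not called with an estimated correlation (adjusted p = 0.299). That setting leaves camera only the few residual degrees of freedom of these libraries, so a set is hard to call there whatever its correlation. The members of the TGF-beta and SMAD list that rose included PMEPA1, TGFBI, BMPR2 and SMAD7. BMPR2, a receptor for bone morphogenetic proteins, rose 2.65-fold from 11.2 ± 0.133 to 29.6 ± 0.33 (adjusted p = 0.0216), and SMAD7, an inhibitor of the pathway, 2.59-fold from 12.5 ± 0.412 to 32.3 ± 3.5 (adjusted p = 0.0222). Adjusted over the list alone, 6 rose and 1 fell. The extracellular matrix list was higher (adjusted p = 0.00272) but not with an estimated correlation (adjusted p = 0.299), with 2 of 11 members passing and 3 adjusted over the list alone. They were FN1 and the basement membrane collagen COL4A1, which rose 3.20-fold from 5.685 ± 2.565 to 18.2 ± 1.97 (adjusted p = 0.0433). COL4A1 did not pass with DESeq2 (adjusted p = 0.0727). With coverage at sites crosslinked in every library its log2 difference was 0.755 against 1.572 (adjusted p = 0.508). The mesenchymal and contractile list was higher (adjusted p = 0.00184) but not with an estimated correlation (adjusted p = 0.32) or by fry (adjusted p = 0.0954), with 1 of 7 passing and 1 adjusted over the list alone, the tropomyosin TPM1, which rose 2.45-fold from 15.9 ± 3.36 to 38.9 ± 4.11 (adjusted p = 0.0291). Without TMM scaling BMPR2, SMAD7, COL4A1 and TPM1 did not pass (adjusted p = 0.521, 0.537, 0.358 and 0.565).

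The Hippo pathway list was not called as a set (adjusted p = 0.635). Of its 11 tested members FRMD6 rose, AMOTL2 fell and 9 did not pass, with 1 and 1 adjusted over the list alone. The angiomotin-like AMOTL2 fell 2.096-fold from 68.8 ± 0.295 to 32.8 ± 2.94 (limma adjusted p = 0.0275, and 0.0568 without TMM scaling). Its log2 difference of -1.05 ranged from -1.581 to -0.9 over 18 settings. Of 7 tested published miR-17 family targets only BMPR2, also in the TGF-beta list, rose, with 1 adjusted over the list alone. That set was not called (adjusted p = 0.246; median log2 difference -0.015, mean 0.33, tested direction higher), but was called higher without control replicate 2 (adjusted p = 0.0378). Among the 7 tested genes of the microRNA machinery list 0 passed by limma and 0 adjusted over the list alone (camera set adjusted p = 0.635). At an unadjusted p under 0.05 there was 1, HMGA2, named after its value was seen. HMGA2 is a chromatin protein and not itself part of that machinery. In that list TNRC6A stood at 36.1 ± 2.53 and 28.7 ± 0.332 and AGO2 at 29.7 ± 5.22 and 21.3 ± 0.752. Among 13 cell cycle genes 0 passed, 0 adjusted over the list alone and 1 unadjusted, CDKN1B (camera set adjusted p = 0.635). With 3' UTR sites alone, or with the replicate number as a block, CDKN1B passed. CDK6 of this list stood at 60.5 ± 16.8 and 52.2 ± 10.8. In the list of abundant non-messenger and mitochondrial RNA, taken as background, 0 of 7 passed and 1 rose adjusted over the list alone. None of these 7 is a mitochondrial RNA. The 1 that rose was RN7SL2, named after its value was seen, on 0 and 3 control reads against 23 and 15 treated reads. RN7SL1, whose name is joined with that of an overlapping gene, had 1 called site but was not in the tested set. That set was not called (adjusted p = 0.175), but was called higher without control replicate 1 (adjusted p = 0.0117) and without TGF-beta1 replicate 2 (adjusted p = 0.00599). Epithelial genes had 3 tested members, too few for the set test, and none passed by limma. The tight junction claudin CLDN1 stood at 14.6 ± 6.79 and 3.69 ± 0.795 (adjusted p = 0.0559). It passed as lower by limma without TMM (adjusted p = 0.0105), with 3' UTR sites only (0.00127) and with coverage at sites crosslinked in every library (0.00391), and by edgeR (adjusted p = 0.0382). Plakoglobin, JUP, stood at 12.9 ± 4.10 and 9.81 ± 3.84. None of the 20 proximal tubule genes and none of the 24 markers of other cell types had a site in the table.

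At the level of single sites, 76 of 1059 tested sites passed, 39 higher and 37 lower, with 61 in 3' UTRs and 8 in coding sequence. They fell in 47 genes, with 6 in UGCG and 4 in FRMD6. FRMD6 had 22 sites, 14 of them in its 3' UTR, 5 in coding sequence, 2 in introns and 1 in its 5' UTR. Only 4 had enough reads for the test, and all 4 rose. These sites passed the low-count filter only with the help of the treated libraries, so the filter itself favoured sites that rose. Their shared direction is therefore not independent agreement between sites. The site with a 7-nt match to the miR-17 family lies in the 3' UTR at position 51728189 of chromosome 14, plus strand. Its window, 51728174 to 51728204, has the sequence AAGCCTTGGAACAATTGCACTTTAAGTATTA, where the match begins 1 nt after the crosslinked T. The window also holds TTGCACT, the 7-nt match of the miR-130 family, which had a 3.67-fold excess in 3' UTR windows. This site rose 10.3-fold, from 1.97 ± 0.350 to 20.3 ± 4.85 scaled RPM (log2 difference 2.83 ± 0.41 SE; limma adjusted p = 6.5e-05). It had 4 and 5 crosslinked reads in the control libraries and 77 and 59 in the treated libraries, and held 27% of FRMD6 crosslinked reads in treated cells. The 3' UTR site at 51728829 rose 4.52-fold (limma adjusted p = 0.00433). Its log2 difference of 1.88 ranged from 1.305 without TMM to 2.515 with coverage at sites crosslinked in every library. The 3' UTR site at 51728280 rose 6.11-fold (limma adjusted p = 0.0139). Its log2 difference of 2.08 became 2.731 with DESeq2, 2.536 without control replicate 1 and 1.578 without control replicate 2. The coding site at 51725833 rose 5.69-fold (adjusted p = 0.00458), and its log2 difference of 2.34 became 1.48 without control replicate 1 and 3.09 without control replicate 2. Without TMM scaling the median site lay at -0.51 on the log2 scale and 4 higher and 24 lower sites passed. Of the 4 FRMD6 sites only the miR-17 family site did (adjusted p = 0.103 for the site at 51725833, 0.261 for 51728829 and 0.161 for 51728280). By limma 102 and 116 sites passed without control replicate 1 or 2, but 2 and 5 without TGF-beta1 replicate 1 or 2, where the miR-17 family site of FRMD6 kept log2 differences of 2.66 and 3.07 but no longer passed (adjusted p = 0.195 and 0.0616), nor did the other 3 FRMD6 sites. With read coverage at sites crosslinked in every library 111 sites passed, among them 59 of the 68 called sites present. With read coverage at all sites 0 sites passed, by limma (863 higher and 237 lower at an unadjusted p under 0.05) and by edgeR.

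**Figure D4:**
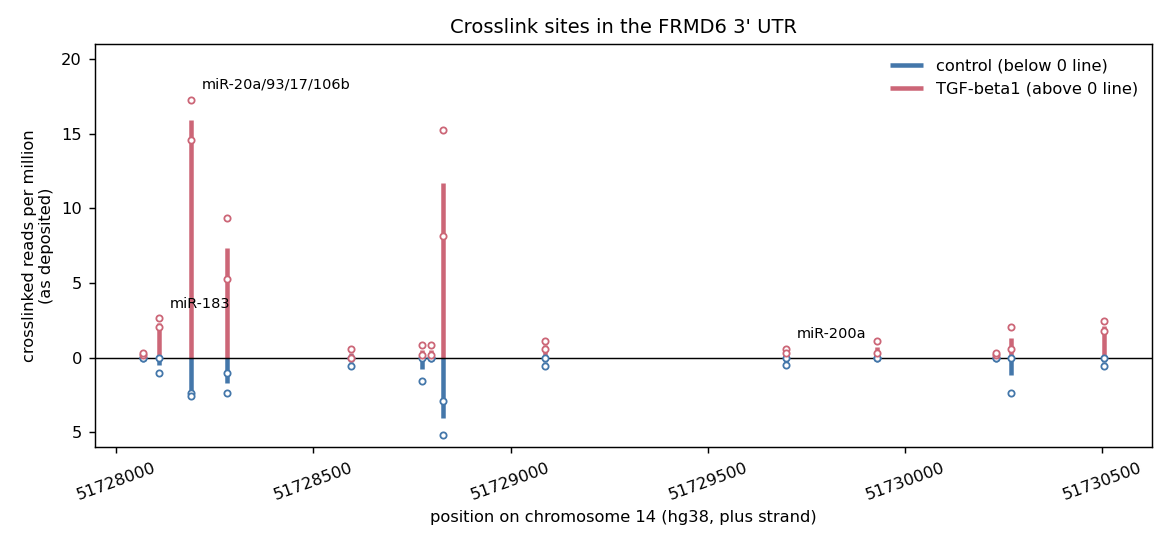
The x axis gives the position on chromosome 14 and the y axis deposited crosslinked RPM at each FRMD6 3' UTR site, with TGF-beta1 libraries above the 0 line and control libraries below it; bars are means of 2 libraries, open circles single libraries, and names mark sites where the authors assigned a 7-nt match. The tallest bar is the miR-17 family site at 51728189, with 14.5 and 17.3 in the treated and 2.33 and 2.60 in the control libraries.

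Sites of a microRNA family were then tested as sets, to ask whether they gained or lost crosslinks together. Of the 50 tested sites of the miR-17 family, 4 rose, 1 fell and 45 did not pass, with a median log2 difference of 0.07. The set was not called (limma camera adjusted p = 0.971). The higher sites included the FRMD6 site. A SEMA7A site at 74409336 of chromosome 15 rose 10.4-fold from 0.793 ± 0.338, on 1 and 3 control reads, to 8.285 ± 0.398 (limma adjusted p = 0.00675). Its log2 difference of 2.38 became 3.318 with DESeq2 and 1.668 with coverage at all sites. An EGR2 site at 62812750 of chromosome 10 rose 4.52-fold from 1.825 ± 1.798, on 1 and 9 control reads, to 8.24 ± 2.076 (adjusted p = 0.0391). Its log2 difference of 1.85 became 1.152 without control replicate 1 (adjusted p = 0.12) and 2.449 without control replicate 2. An ANKRD33B site at 10651603 of chromosome 5 fell 4.71-fold from 9.218 ± 1.845 to 1.956 ± 1.151, on 9 and 4 treated reads (adjusted p = 0.0243). Its log2 difference of -1.83 became -2.325 without TGF-beta1 replicate 1 and -1.643 without control replicate 1 (adjusted p = 0.239 and 0.12). None of these 3 sites passed without TGF-beta1 replicate 1 or 2. Without TMM scaling SEMA7A and EGR2 did not pass (adjusted p = 0.117 and 0.284), and with DESeq2 EGR2 and ANKRD33B did not (adjusted p = 0.139 and 0.0523). Adjusted over that set alone, 8 rose and 4 fell, while of 61 tested sites that the authors annotate with this family 6 rose and 6 fell, with a median of -0.014. Of the 18 families with at least 10 tested sites 0 passed by camera with the preset correlation or by fry. The smallest unadjusted p was 0.0967 by this camera test, for miR-19, and 0.0366 by fry, for miR-96. With an estimated correlation camera called 0 as well, but its few residual degrees of freedom left little chance of a call.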

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

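The edgeR test, other pseudocounts, the spread without a trend, coverage, thinning, every seed setting, and leaving out libraries in the set and location results were chosen after the data were seen. From 76 sites, the count past the threshold became 42 with DESeq2, 28 without TMM and a median of 48.5 after thinning. Without the trend it was 25, with 20 higher and 5 lower. It was 0 without a filter on low counts (limma; 1994 higher and 310 lower at an unadjusted p under 0.05), and ranged from 2 to 116 when a library was left out. From 39 genes it became 4 without the filter, 3 without the trend and 70 with 3' UTR sites only, and ranged from 0 to 17 when a library was left out. Those fits have 1 residual degree of freedom, and the lone library is assumed to vary like the other group. Coverage at sites crosslinked in every library gave 111 sites and 103 genes. Coverage at all sites gave 0 sites and 25 genes by limma, and 0 and 19 by edgeR. By edgeR 693 sites were higher and 159 lower at an unadjusted p under 0.05. Without the trend it gave 512 sites, 484 higher and 28 lower, and 16 genes. Without TMM it gave 623 sites, 577 higher and 46 lower, and 12 genes. Each of these 2 settings kept 4 of the 76 called sites. Of the 39 called genes, limma kept 17, edgeR 15, limma without the trend 5 and limma without TMM 10. There a library without a crosslink has a coverage of 0, and fewer reads in the control libraries give more such 0s. The replicate number as a block gave 117 sites and 57 genes. Deviations of same-numbered libraries from their group means correlated at 0.117 over sites and 0.131 over genes, and the block changed no set call. It added CLDN1 (adjusted p = 0.0322), CDKN1B (0.0299) and NEAT1 (0.0322). Coding sites gave 22 families with excess seed matches and intronic sites 7, against 32. The 3 list calls became 0 with an estimated correlation. That correlation was -0.0111 for the TGF-beta and SMAD list and -0.066 for the matrix list, both under the preset 0.01. A higher correlation between members therefore does not explain these 2 losses. For the mesenchymal and contractile list it was 0.151, above the preset. With an estimated correlation camera also refers its statistic to the few residual degrees of freedom of 4 libraries, which the preset does not. A set is therefore far harder to call there, whatever its correlation. What caused the other changes was not tested further, except that testing all sites adds features with few reads and leaving out a library removes a sample. For the 26 called genes and FRMD6 sites named in advance by rule, the call held in 263 of 463 comparisons over 18 settings, was reversed in 0 and lost in the rest. Among named genes that did not pass, the log2 difference changed sign without TMM for ZFP36L1 (-0.139), DCBLD2 (-0.269) and MALAT1 (-0.391). It did so with 3' UTR sites only for TNRC6A (0.086) and IRS2 (0.003), and without the filter for IRS2 (0.018). For MALAT1 it was -0.031 with coverage at sites crosslinked in every library, and at all sites -0.043 with or without the trend, -0.258 without TMM and -0.022 by edgeR. Leaving out a library gave -0.469 to 0.088 for CDK6, -0.327 to 0.08 for IRS2 and -0.327 to 0.649 for MALAT1. Family sets stayed at 0 calls in every setting run. The 3' UTR share differed by -8.36 to -0.88 percentage points when a library was left out. The fit of all 6 libraries, every IgG comparison, the 40 nt window and the downstream control window were not run. In reads simulated at this depth, with a spread set by level alone, 18% of 2-fold changes were recovered for genes and 14% for sites. Thinning left a median of 40.5 genes.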

Other observations

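The tests of the gene calls and of the FRMD6 site were chosen only after those results were seen; the tests of the DCBLD2 sites were fixed before their values were seen. Intronic crosslinks were concentrated in a few genes. DCBLD2 held 323 of the 3586 intronic sites, 9.0% of them. Others included PLCB4 with 77, TRIO with 69 and BICC1 with 55, genes named after their values were seen. In DCBLD2, on the minus strand of chromosome 3 from 98795941 to 98901695 (GRCh38.p14), the intronic sites carried 1986 crosslinked reads, a median of 5 per site, and 9.3% had a 7-nt seed match.

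Of the miR-29 family, the authors' table gives the seed as TAGCACC, which is nucleotides 1 to 7 of the mature sequence used here, not 2 to 8. The match to nucleotides 2 to 8, TGGTGCT, occurred in 167 of the 6332 3' UTR windows and the match to the listed seed, GGTGCTA, in 61, with 43 windows holding both. Of 241 sites that the table annotates with a 6-nt match to the end of this seed, 187 hold the 7-nt match to nucleotides 2 to 8. One is the FRMD6 site at 51728829, in the sequence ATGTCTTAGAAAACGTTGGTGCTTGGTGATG. Some families absent from the authors' seeds also had an excess of matches, such as miR-15/16 at 5.27-fold and miR-19 at 5.05-fold; the miR-15/16 match overlaps that of miR-103 and miR-107.

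For the DCBLD2 sites, 3 explanations were weighed and the values argue against each as the whole cause. Reads from DNA would fall on both strands, but 0.0% of the 426 sites within the gene's bounds lay on the opposite strand. Gene length could give more sites, but DCBLD2 had 3.05 intronic sites per kb against a 99th percentile of 0.347 among 1104 other genes of at least 10 kb. Those genes had at least 1 intronic site. DCBLD2 was picked from the same data for its many intronic sites, which made a high rank per kb likely. An unannotated exon would gather the sites, but the fullest 5 kb bin held 12.4% of them and 21 of 22 bins held at least 1. The amount of unspliced RNA was not measured here and stays open, so no biological explanation was tested.

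For the 39 genes called between control and treated cells, depth and scaling were weighed. With every library thinned to the shallowest, a median of 34 of the 39 still passed, from 24 to 38 over 20 draws. Thinning leaves the expected differences as they were and does not undo a site list that follows the deeper treated libraries, so how much depth decides stays open. Without TMM factors 20 of the 39 still passed, so how much of the list scaling decides stays open too. Directions test neither, since no called gene had a log2 difference under 0.934 in size. A candidate explanation is a change in the amount of each RNA: the log2 differences of 512 sites in 184 genes with several tested sites had an intraclass correlation of 0.666 within genes (permutation p = 1e-04, the smallest it can give). It was 0.35 without the called genes (permutation p = 1e-04). Differences between libraries unrelated to TGF-beta1 would also move a gene's sites together, so neither value ties the shift to treatment. By edgeR's diffSpliceDGE, which sets each site against its gene as a whole, 0 sites differed, with 10 at an unadjusted p under 0.05. RNA amounts were not analysed here, so a change in Argonaute binding spread over a whole transcript stays open.

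The last hypothesis was that the miR-17 family site of FRMD6 changed beyond the gene as a whole. On the natural log scale of edgeR's test its difference exceeded that of the gene, this site included, by 0.50 (edgeR adjusted p = 0.999). By edgeR its log2 difference was 3.368, against 2.138 to 2.724 at the gene's other tested sites. With 9 control reads at the site the counts are too few to decide, so a change of occupancy at this site and a change in FRMD6 RNA cannot be told apart with these values. Nor can the miR-17 family and the miR-130 family, whose match lies in the same window.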
